A study of Mus musculus with 64 samples.

How the data were processed

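Total RNA from the whole brain of 32 adult male mice was labelled as biotinylated cRNA and hybridised to Affymetrix mouse 430A 2.0 arrays. The 8 groups are 2 strains, C57/B6 and Balb/C, on 4 days (uninfected on day 0, and days 1, 3 and 6 after infection), with 4 mice each. The labels number 4 biological replicates per group and 2 technical replicates per mouse, so a mouse is the unit of replication and its 2 arrays (64 in all) are technical. All 64 columns were assigned to a group from their labels, with 0 columns unmapped.

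The deposited values are intensity values per probe set on a linear scale, from 8.998 to 22380, summarised by RMA per the submitters' processing notes (version not given in the sources used here). They were positive, and the array medians lay between 78.82 and 82.91, so that the arrays had been brought to a common level by the authors. RMA values are usually given as log2, and the range of these shows that they are not; log2 was therefore taken first, as had been foreseen for linear values. All changes are given as log2 fold changes of intensity. No further normalization was applied.

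Of the probe sets, 64 array controls were left out of the tests and used as quality measures. The array annotation lists 21071 probe sets, of which 20380 carry 1 gene symbol and 691 carry several, and 1555 probe sets had no gene. Each gene was represented by the probe set with the highest mean log2 value over all arrays among those with that symbol alone, which gave 12393 genes, 4956 of which had more than 1 probe set. Probe sets of no gene or of several genes were left out of the comparisons and examined apart. No low-value filter was used.

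The 2 arrays of a mouse were averaged on the log2 scale. A linear model with a mean for each of the 8 groups was fitted to the 32 mice with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with 24 residual degrees of freedom and 5.545 prior degrees of freedom. The 13 contrasts were each day against day 0 within a strain, the strains against each other on each day, and the interaction, which is the change in C57/B6 minus the change in Balb/C mice. P values were adjusted by the Benjamini-Hochberg method over all genes within a contrast, and a gene was called at an adjusted p under 0.05. Errors of fold changes are SE from this model, and errors of levels are SD between 4 mice. The labels give no batch, date or position on a chip, so none was tested, and the technical arrays give the only repeat measure. The median over genes of the SD between the 2 arrays of a mouse was 0.142 and that between the mouse means of a group 0.12. The number of arrays limits the precision.

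These choices, the 36 gene lists with 668 members (579 measured) and the rule for naming genes were made before the data were examined. The rule names, for each strain on day 6 and for the day 6 interaction, the 10 largest rises and falls among called genes. For day 1, day 3 and the uninfected strains it names 5 in each direction, and for all of these but the interaction the 4 mice of a group must lie on the same side of all 4 mice of the other. It adds up to 4 members of each list with the largest absolute log2 fold changes and a fixed set of genes of cerebral malaria (Ifng, Gzmb, Prf1, Cd8a, Cxcl9, Cxcl10, Ccl5, Tnf, Icam1, Vcam1, Selp, Lcn2, Hmox1, Gfap, Hbb-b1 and Alas2). Hbb-b1 had no probe set of its own. H2-Ea was added as a check of the strain labels. The lists cover interferon-stimulated genes, interferon-gamma-induced genes, antigen presentation by MHC class I and class II, chemokines, cytokines and complement. They also cover markers of T cells, B cells, monocytes, neutrophils, microglia, astrocytes (resting and reactive), oligodendrocytes, neurons, endothelial cells (resting and activated), pericytes, erythroid cells, platelets, choroid plexus, meninges, pituitary, olfactory bulb and cerebellum. The other lists hold immediate-early, glucocorticoid-responsive, hypoxia-inducible, heme and iron, cell cycle, cholesterol, unfolded protein, heat shock, circadian and oxidative phosphorylation genes.

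Lists were tested with camera from limma, with a preset correlation of 0.01 between genes, two-sided and adjusted over the lists within a contrast. As alternatives camera was run with the correlation estimated from the data, and fry with its directional and mixed tests. Members called were counted over all genes and adjusted over the list alone.

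Whether replicate numbers pair mice across groups is not stated in the labels. It was checked once per contrast by correlating, over genes, the deviations from the group means of mice with the same number. The numbers were taken as paired where all 4 correlations were above 0.1, as in C57/B6 mice on day 1 (0.12 to 0.64) and day 3 (0.18 to 0.63) and in Balb/C mice on day 6 (0.19 to 0.54). For these the value with the replicate number as a block is given beside the count. The counts with the block were printed in the same run as this check, and the rule was applied without regard to them.

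The fit and the lists were tested on simulated data with 200 genes changed in C57/B6 mice on day 6 against day 0. Of the genes changed by 2-fold 100% were called and of those changed by 1.5-fold 93%, while 7.66% of the calls were unchanged genes. In the 5 unchanged comparisons with day 0 the highest number of genes called was 0. Simulated genes and mice were drawn independently, with no poorly correlated array and no likeness of mice that share a number. These rates therefore need not hold for the real data.

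Alternatives tried were median-centring of each array, a further quantile normalization, a low-value filter (7368 genes kept), the mean of all probe sets of a gene, and leaving out probe sets with the suffixes s, x and a (10529 genes). Others were each technical replicate alone, all arrays with the mouse as a random block (statmod 1.5.0, correlation 0.167), array quality weights, a model of the groups of a contrast alone, the replicate number as a block, stricter thresholds, and leaving out each mouse in turn. After seeing the data, 1 array with a low correlation to its duplicate, and that array with another of a high 3′ to 5′ ratio, were left out, the first also together with the block. For each count of genes, all 35 splits of the 8 mice of a contrast into groups of 4, or 100 splits drawn with a fixed seed for an interaction, were counted in the same way.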

Results

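Gene expression was measured in the brain of adult male mice of the C57/B6 strain, which is susceptible to cerebral malaria caused by Plasmodium berghei ANKA, and of the resistant Balb/C strain. Mice were uninfected (day 0) or were studied on day 1, 3 or 6 after an intraperitoneal injection of 500000 parasitised erythrocytes. Each of the 8 groups of 1 strain and 1 day held 4 mice, and 2 arrays were made for each mouse, so that 64 arrays described 32 mice. The median intensity of an array lay between 78.82 and 82.91. For each of 12393 genes the 2 arrays of a mouse were averaged on the log2 scale, and n = 4 mice in every group below. The number of arrays limited the precision, and the median standard error (SE) of a log2 fold change between a pair of groups was 0.084. A gene is said to have risen or fallen where its adjusted p from limma was under 0.05.

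The first question was what had changed in the brain of susceptible mice by day 6. In C57/B6 mice the largest rises were of interferon-induced genes. Gbp2, a guanylate-binding protein induced by interferon-gamma, rose by a log2 fold change of 5.19 ± 0.32 (SE), from a log2 intensity of 4.68 ± 0.17 (SD, n = 4) in uninfected mice to 9.87 ± 0.16 on day 6. The immunity-related GTPases Iigp1 (4.70 ± 0.40), Igtp (4.12 ± 0.31) and Irgm1 (3.91 ± 0.23) also rose, as did the antiviral genes Ifit3 (4.14 ± 0.26), Oasl2 (3.88 ± 0.24) and Ifit1 (3.87 ± 0.27). Cxcl10, a chemokine that attracts activated T cells, rose from 4.98 ± 0.08 to 8.87 ± 0.08, and Lcn2, an iron-binding acute-phase protein, rose from 4.22 ± 0.14 to 8.28 ± 0.41. Granzyme B (Gzmb), a protease of cytotoxic lymphocytes, rose from 4.75 ± 0.05 to 8.17 ± 0.88. In uninfected C57/B6 mice Lcn2 was higher than 7.6% of genes, Gbp2 than 17%, Gzmb than 18% and Cxcl10 than 23%, and no test separated these levels from background, so the changes are differences of intensity and not of transcript number. Among genes whose infected and uninfected mice did not overlap, the largest falls were of the endothelial marker Itm2a (log2 fold change -2.22 ± 0.20), the microglial receptor P2ry12 (-2.18 ± 0.24), the glial fatty-acid-binding protein Fabp7 (-1.90 ± 0.29), the myelin lipid enzyme Ugt8a (-1.84 ± 0.24), Serpinb1a (-1.81 ± 0.13), the thyroid hormone transporter Slco1c1 (-1.68 ± 0.14) and Trim59 (-1.59 ± 0.16).

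Among the 27 measured type I interferon-stimulated genes, 26 rose, with a median log2 fold change of 1.80, and 27 did so when adjusted over the list alone. Of the 18 interferon-gamma-induced GTPases and effectors, 14 rose (14 adjusted over the list alone, median 2.00). All 13 genes of MHC class I antigen presentation rose (13 adjusted over the list alone, median 1.48), among them the peptide transporter subunit Tap1 (log2 fold change 2.41 ± 0.12), the immunoproteasome subunits Psmb9 (2.59 ± 0.19) and Psmb8 (2.38 ± 0.18), and B2m (1.65 ± 0.19). Of the 9 MHC class II genes 7 rose (7 adjusted over the list alone), including the invariant chain Cd74 (1.91 ± 0.19) and H2-Aa (1.44 ± 0.20). The camera test of lists against all other genes gave adjusted p values of 6.3e-43, 2e-22, 8.9e-20 and 1.7e-06 for these 4 lists, and 7e-04, 0.0029, 0.0028 and 0.012 with an estimated correlation between genes.

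Of the 17 monocyte and macrophage markers 9 rose (9 adjusted over the list alone), including Plac8 (log2 fold change 2.42 ± 0.08), Fcgr4 (1.13 ± 0.09) and Chil3 (1.10 ± 0.19), with a camera adjusted p of 3.3e-06, and 0.0029 with an estimated correlation. Of the 24 T cell and cytotoxic lymphocyte markers 13 rose (14 adjusted over the list alone, median 0.20), including Gzma (2.70 ± 0.12), Nkg7 (0.75) and Cd3d (0.47 ± 0.10). This list passed camera (adjusted p = 2.3e-07), but the call was lost with an estimated correlation (adjusted p = 0.24). For Prf1 (0.07, adjusted p = 0.52) and Cd8a (0.17, adjusted p = 0.25) no change was called, although the Cd8a call was made when all probe sets of the gene were averaged and when day 6 mouse 2 was left out. Of the 22 chemokines 10 rose and Cxcl12 fell (15 and 1 adjusted over the list alone), and Ccl12 (2.16 ± 0.21), Cxcl9 (1.88 ± 0.11) and Ccl5 (1.05 ± 0.15) were among those that rose. The camera adjusted p for chemokines was 3.3e-06, and adjusted p = 0.098 with an estimated correlation. Of the 23 cytokines 4 rose and the alarmin Il33 fell (-0.92 ± 0.22), the same counts as those adjusted over the list alone, with a camera adjusted p of 0.00079 and an adjusted p of 0.23 with an estimated correlation. Those that rose were Ifng, Csf1 (0.76), Il18bp (0.94) and Tnfsf10 (0.24), the last named after its values were seen. Interferon-gamma itself (Ifng) rose from 3.94 ± 0.04 to 4.44 ± 0.15, among the lowest intensities on the array, and Tnf was not called (0.18, adjusted p = 0.063).

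All 17 glucocorticoid-responsive genes rose (17 adjusted over the list alone, median 1.27), including the cell-cycle inhibitor Cdkn1a (log2 fold change 2.49 ± 0.13), the glucocorticoid receptor co-chaperone Fkbp5 (2.21 ± 0.11) and the lipid droplet protein Plin4 (1.90 ± 0.07). The list passed camera with an adjusted p of 2.2e-24, and of 7e-04 with an estimated correlation. Of the 20 reactive astrocyte genes 11 rose (11 adjusted over the list alone, with 1 fall), including Osmr (1.20 ± 0.13), the ceruloplasmin gene Cp (0.82) and Gfap, the intermediate filament of astrocytes (0.60 ± 0.14, adjusted p = 0.0025). Lcn2 and Fkbp5 are on both of these lists and Cxcl10 is on the lists of reactive astrocyte genes and chemokines. Of the 20 complement and coagulation genes 14 rose (16 adjusted over the list alone), including Serping1 (1.36 ± 0.15) and C1qb (0.75 ± 0.17). Of the 19 endothelial activation and adhesion molecules 11 rose and thrombomodulin (Thbd) fell (-0.65 ± 0.13), or 12 and 1 adjusted over the list alone. Icam1 (1.13 ± 0.13), Lrg1 (1.31 ± 0.10) and Itgb2 (0.82) were among the 11, whereas Vcam1 (-0.15, adjusted p = 0.62) and Selp (0.19, adjusted p = 0.087) were not called. These last 3 lists passed camera with adjusted p values of 5.4e-09, 9.2e-07 and 8.6e-06, and of 0.0011, 0.0011 and 0.0083 with an estimated correlation.

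A further group of lists passed camera with its preset correlation alone. Of the 17 genes of mitochondrial oxidative phosphorylation 12 fell (13 adjusted over the list alone), among them Ndufa9 (log2 fold change -0.44) and Ndufa4 (-0.40 ± 0.06), and of the 14 genes of cholesterol synthesis 9 fell (9 adjusted over the list alone), among them Cyp51 (-0.68 ± 0.14) and Sqle (-0.57 ± 0.10). Their camera adjusted p values were 3.1e-06 and 4.5e-05, and each adjusted p with an estimated correlation was higher, at 0.19 and 0.08. Of 23 cell cycle genes 11 rose (14 adjusted over the list alone), including Ube2c (0.52 ± 0.11) and Birc5 (0.42), with a camera adjusted p of 3.3e-06 and an adjusted p of 0.17 with an estimated correlation. Of 11 oligodendrocyte markers Mobp rose and 5 fell (1 and 6 adjusted over the list alone), including Gpr37 (-1.25 ± 0.09) and Aspa (-1.14 ± 0.12), with adjusted p = 0.0053 by camera and adjusted p = 0.24 with an estimated correlation. Of 13 choroid plexus markers 1 rose and 6 fell (1 and 6 adjusted over the list alone), including Folr1 (-1.02 ± 0.13) and Sostdc1 (-1.01), and of 12 meningeal fibroblast markers 7 fell (9 adjusted over the list alone), including Lum (-0.54). Their camera adjusted p values were 0.0052 and 0.0046, and adjusted p = 0.32 and 0.42 with an estimated correlation. Of 12 cerebellum markers 8 fell (10 adjusted over the list alone), including Gabra6 (-1.26 ± 0.35), with adjusted p = 0.0016 by camera and 0.47 with an estimated correlation. Day 6 mouse 2 had the lowest mean of this list, 7.50 against 8.72 for the nearest of the other mice, and without it the camera adjusted p was 0.12. Day 6 mouse 4 had the lowest means of oxidative phosphorylation (11.27) and cholesterol synthesis genes (7.92) and the highest of cell cycle genes (5.19) among the day 6 mice. Its second array was poorly correlated with its first, and without that array all 19 lists that passed camera still passed.

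Markers of microglia, endothelial cells, astrocytes, neurons and pericytes did not pass camera in C57/B6 mice on day 6, and each list had members that rose and members that fell. Over all genes 28.6% were called, with 1393 rises and 2155 falls, so calls in both directions do not by themselves set these lists apart. Of the 17 microglia markers 4 rose and 5 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.43), with falls of P2ry12, Gpr34 (log2 fold change -1.40 ± 0.16) and Fcrls (-1.07 ± 0.10) beside the rise of C1qb. Of the 20 endothelial cell markers 4 rose and 6 fell (6 and 6 adjusted over the list alone, adjusted p = 0.76), with Pecam1 (0.64 ± 0.07) and the glucose transporter Slc2a1 (0.67 ± 0.13) higher and Itm2a and Slco1c1 lower. The median of the endothelial list was 0.01 and its mean -0.13, the direction that camera gave. Of the 13 astrocyte markers 3 rose and 2 fell (3 and 2 adjusted over the list alone, adjusted p = 0.44), with the gap junction gene Gjb6 (0.74 ± 0.09) higher and the water channel Aqp4 (-0.63 ± 0.12) lower. Of the 19 neuron markers 4 rose and 2 fell (4 and 2 adjusted over the list alone, adjusted p = 0.43), with Nefh (0.88) higher and Pvalb (-0.55 ± 0.14) lower, and of the 12 pericyte and smooth muscle markers 1 rose and 3 fell, including Vtn (-0.84), also adjusted over the list alone (adjusted p = 0.38).

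The remaining lists did not pass camera on day 6 in C57/B6 mice. Of 17 erythroid cell markers 1 rose and 4 fell, also adjusted over the list alone, including Alas2, the erythroid enzyme of heme synthesis (log2 fold change -1.37 ± 0.21), with a median of 0.03, a mean of -0.05 and a downward camera adjusted p of 0.8. Of 11 B cell markers none rose or fell (adjusted p = 0.56), of 12 neutrophil markers Fpr2 rose (adjusted p = 0.32), and of 10 platelet and megakaryocyte markers 1 rose and 2, Pf4 (-0.30) and Ppbp (-0.28), fell (adjusted p = 0.99), with the same counts adjusted over the list alone. The 19 heme, iron and oxidative stress genes had 5 rises, including heme oxygenase Hmox1 (0.42 ± 0.10, adjusted p = 0.0015), and 3 falls, including the iron exporter Slc40a1 (-1.04 ± 0.12), or 5 and 4 adjusted over the list alone (adjusted p = 0.71). Hypoxia-inducible and glycolytic genes had 5 rises, including Ddit4 (1.03) and Pfkfb3 (0.94), and 5 falls among 19, also adjusted over the list alone, with a median of -0.09, a mean of 0.06 and an upward camera adjusted p of 0.99. Among 16 genes of the unfolded protein response 2 rose and 6 fell, including Xbp1 (-0.86), or 2 and 7 adjusted over the list alone (adjusted p = 0.25). The 12 heat shock proteins had 1 rise, Hspb1 (0.74), and 2 falls (adjusted p = 0.45), and the 19 immediate-early genes had 4 rises, including Zfp36 (0.99), and 1 fall, Dusp6 (-0.62, list adjusted p = 0.36). The 14 circadian clock genes had 3 rises, including Tef (0.45), and 1 fall (adjusted p = 0.43), Pitx1 (0.39) alone rose among 9 pituitary markers (adjusted p = 0.22), and Calb2 (-0.62) alone fell among 9 olfactory bulb markers (adjusted p = 0.99), with the same counts adjusted over each list alone.

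In all, 3548 genes (28.6%) passed limma in C57/B6 mice on day 6, of which 1393 rose and 2155 fell, and 117 rose and 33 fell by at least 2-fold. The second array of day 6 mouse 4 correlated with the mouse's first array at 0.9291, against at least 0.9866 in every other mouse. Without that array, a step chosen after seeing the data, 1449 genes rose and 1730 fell, and with a model of the day 0 and day 6 mice alone 429 rose and 392 fell. The calls on Acta2 (-0.41), Pitx1 and Aldh1l1 (0.33) were among those that other choices ended.

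**Figure D1:**
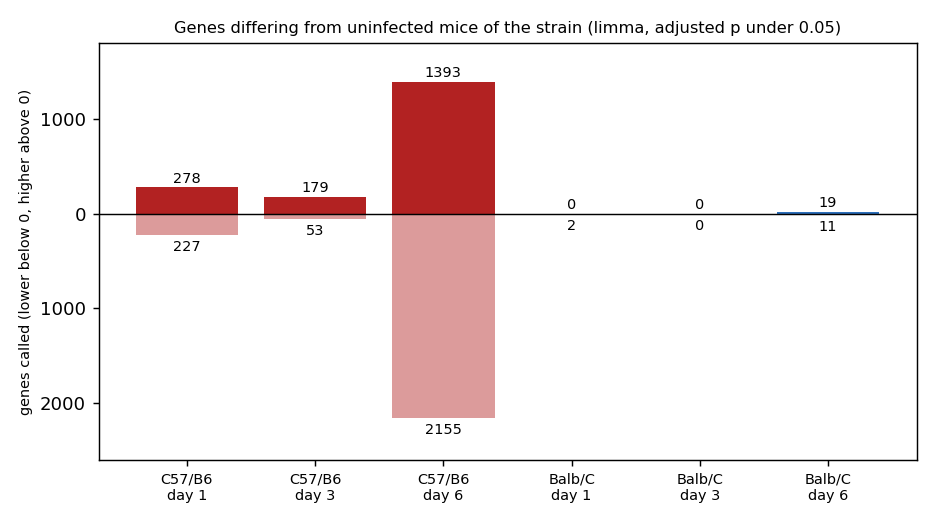
Bars give the number of genes higher and lower than in uninfected mice of the same strain at an adjusted p under 0.05, by day after infection, for C57/B6 and Balb/C mice (4 mice per group). On day 6 there were 3548 such genes in C57/B6 and 30 in Balb/C mice.

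The same day was examined in resistant mice. In Balb/C mice 30 genes passed on day 6, of which 19 rose and 11 fell, and 501 had an unadjusted p under 0.05. The genes that rose most were interferon-induced. Iigp1 rose by a log2 fold change of 2.46 ± 0.40 (SE, n = 4), Gbp2b by 2.21 ± 0.35, Gbp2 by 1.99 ± 0.32 and Igtp by 1.90 ± 0.31, followed by Irgm2 (1.42), Ifit1 (1.39), Irgm1 (1.31 ± 0.23), AW112010 (1.29 ± 0.20) and Rtp4 (1.25). These SE come from a spread pooled over all 8 groups and understate the spread of Iigp1 and Gbp2 in the Balb/C day 6 mice. The SE of the other interferon-induced genes may be too small for the same reason. In these mice the means of the type I and interferon-gamma lists had an SD of 0.4 and 0.52, against 0.07 and 0.06 in C57/B6 day 6 mice. The Balb/C mice varied widely, and on day 6 the log2 intensity of Iigp1 was 7.13 ± 1.59 (SD) and that of Gbp2 6.41 ± 1.32. In mouse 4 they were 4.80 and 4.53, each above the 4 uninfected mice by less than 0.1, and in the other 3 mice 7.53 to 8.31 and 6.49 to 7.49. The 11 genes that fell included several of myeloid cells, namely P2ry12 (-1.14 ± 0.24), the Fc receptor Fcgr3 (-0.75 ± 0.11), Cd53 (-0.65), Cd68 (-0.51), Tyrobp (-0.50) and Trem2 (-0.40), together with Thbd (-0.72 ± 0.13) and Cxcl12 (-0.46).

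Of the 18 interferon-gamma-induced GTPases and effectors 9 rose in Balb/C mice on day 6 (13 adjusted over the list alone, median 0.55), and of the 27 type I interferon-stimulated genes 6 rose (19 adjusted over the list alone, median 0.31). Of the 13 MHC class I genes Psmb8 (0.90) rose (8 adjusted over the list alone, median 0.23). Of the 17 microglia markers 4 fell (10 adjusted over the list alone, median -0.33), and all 17 had negative log2 fold changes. These 4 lists passed camera, with adjusted p values of 2.1e-32, 1.7e-35, 1.5e-15 and 3.4e-27, and of 0.001, 0.001, 0.012 and 0.00052 with an estimated correlation. The 13 choroid plexus markers had no call over all genes and 3 falls adjusted over the list alone (median -0.19), with a camera adjusted p of 8.2e-09, and 0.047 with an estimated correlation. A further 12 lists passed camera with its preset correlation alone, each with an adjusted p of at least 0.088 with an estimated correlation. They included meningeal fibroblast markers (median -0.22) and cerebellum markers (-0.26), and 10 of them lost the call with 1 mouse left out.

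Several genes with large rises in C57/B6 mice were not called in Balb/C mice. Cxcl10 had a log2 fold change of 0.56 (adjusted p = 0.33), Cxcl9 0.30 (adjusted p = 0.9), Lcn2 0.29 (adjusted p = 1) and Gzmb 0.08 (adjusted p = 1). Vcam1 (0.42), Icam1 (0.11), Ifng (0.10), Ccl5 (0.09), Selp (0.05), Prf1 (0.03), Hmox1 (0.01), Cd8a (0), Tnf (-0.06), Gfap (-0.10) and Alas2 (-0.48) were also not called. The calls of both strains share the estimate of spread of each gene, so they are not fully independent. Of the 19 genes that rose in Balb/C mice 18 also rose in C57/B6 mice, where 2.14 would be shared if the strains were independent (Fisher's exact test, one-sided toward more sharing, p = 1.3e-16). Of the 11 that fell 5 also fell in C57/B6 mice, where 1.91 would be shared (p = 0.029 by the same exact test). Both p values take genes as independent, although most of the 19 that rose are interferon-induced and can change together. They therefore do not measure how well the sharing repeats over mice. The Balb/C count was 15 without day 6 mouse 1, 16 without day 6 mouse 2 and 46 without day 6 mouse 4. It was 44 with the replicate number as a block, and 4 with a model of the day 0 and day 6 Balb/C mice alone. All 4 of these fell (Cldn5, Fcgr3, Frmd6 and Gpr34), so none of the 19 rises was called in that model, and of the 30 calls only that on Fcgr3 was made again.

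**Figure D2:**
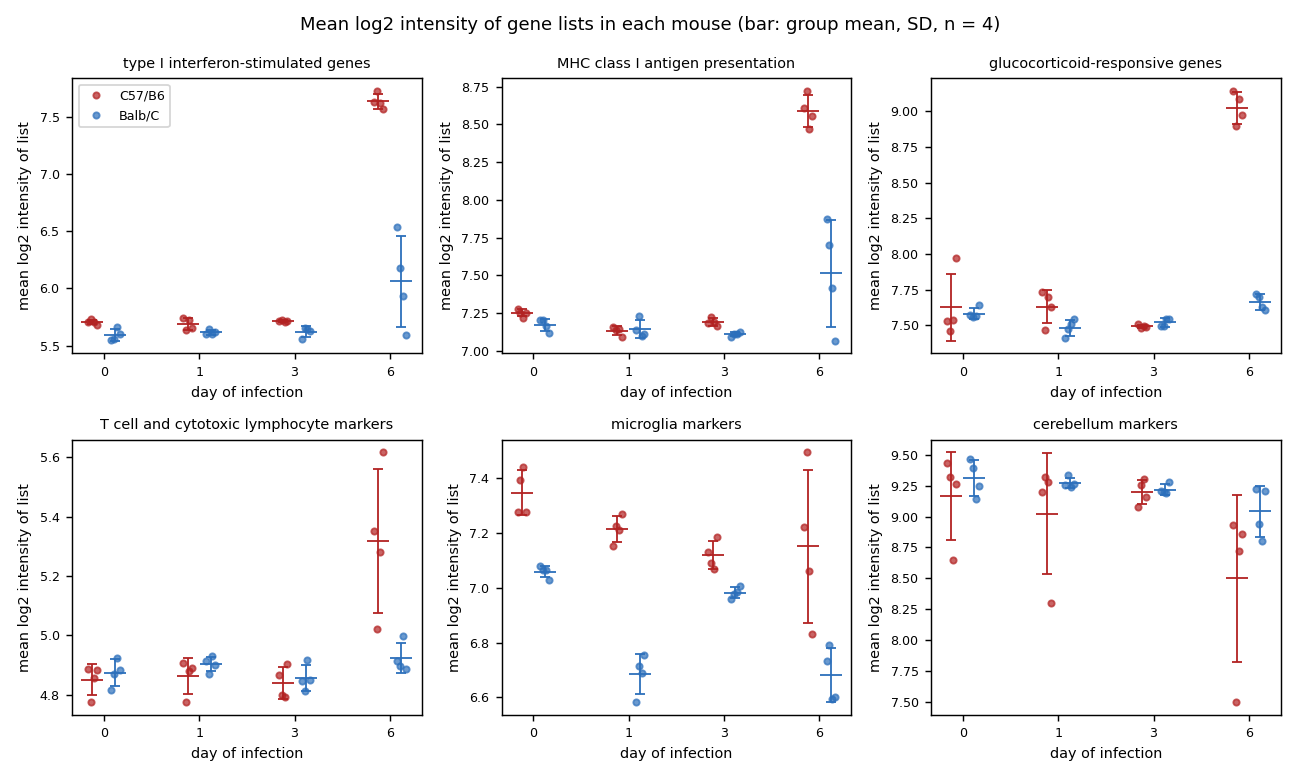
Each point is the mean log2 intensity of a gene list in 1 mouse, by strain and day after infection, with bars at the group mean and its SD (n = 4 mice). The type I interferon-stimulated genes lay between 7.57 and 7.73 in C57/B6 mice and between 5.59 and 6.54 in Balb/C mice on day 6.

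Whether the response to infection differed between the strains was tested by the interaction of strain and infection. On day 6 this passed for 1050 genes, 497 with a positive value (a log2 fold change further upward in C57/B6 than in Balb/C mice) and 553 with a negative value. Among those of at least 1.5-fold 226 were positive and 138 negative, and among those of at least 2-fold 113 and 15. Of the 497, 485 had risen in C57/B6 mice, and of the 553, 546 had fallen in C57/B6 mice. The largest positive interaction was that of Lcn2 (log2 difference 3.77 ± 0.27, SE). It was followed by Gbp6 (3.35 ± 0.20), Gzmb (3.34 ± 0.29), Cxcl10 (3.33 ± 0.23), Gbp2 (3.20 ± 0.46), Oasl2 (2.95 ± 0.33), Ifit3 (2.92 ± 0.37), Ctla2a (2.80 ± 0.23), Irgm1 (2.60 ± 0.33) and Cdkn1a (2.59 ± 0.18). For interferon-induced genes these SE, from the same pooled spread, may be too small, since the Balb/C day 6 mice varied widely. The interaction also passed for Gzma (2.55 ± 0.16), Plac8 (2.27 ± 0.11), Icam1 (1.02 ± 0.18), Ccl5 (0.97), Gfap (0.70 ± 0.20, adjusted p = 0.031) and Ifng (0.39 ± 0.09, adjusted p = 0.0066), and was not called for P2ry12 (-1.04, adjusted p = 0.053), Alas2 (-0.89, adjusted p = 0.054) or Hmox1 (0.41, adjusted p = 0.058). The Gfap call and the Ifng call ended under at least 1 alternative. Negative interactions were led by Gbp2b (-2.07 ± 0.49), Fabp7 (-1.97 ± 0.41), Itm2a (-1.90 ± 0.28), Ugt8a (-1.79 ± 0.34), Serpinb1a (-1.71 ± 0.19) and Slco1c1 (-1.57 ± 0.19), followed by Trim59 (-1.39 ± 0.23), Nectin3 (-1.18 ± 0.21), Gpr37 (-1.18 ± 0.12) and Aspa (-1.11 ± 0.18).

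Gbp2b was called in Balb/C mice only, and its log2 intensity in C57/B6 mice was 4.14 ± 0.06 (SD) when uninfected and 4.28 ± 0.10 on day 6. Fcgr3 and Cyba were the 2 genes called in both strains with opposite signs. Fcgr3 rose by 1.18 in C57/B6 and fell by 0.75 in Balb/C mice, and Cyba rose by 0.54 and fell by 0.41. Of the 19 genes that rose in Balb/C mice, 17 rose more in C57/B6 mice by the interaction.

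By list, 9 of the 18 that passed camera for the day 6 interaction also passed with an estimated correlation. Interactions were positive for 24 of 27 type I interferon-stimulated genes (25 adjusted over the list alone, median 1.5), 14 of 18 interferon-gamma-induced genes (14, median 1.24), 11 of 13 MHC class I genes (13, median 1.08) and 4 of 9 MHC class II genes (6, median 0.34). They were positive for 12 of 17 glucocorticoid-responsive genes (15 adjusted over the list alone, median 1.10), 10 of 20 reactive astrocyte genes (12, median 0.57) and 9 of 20 complement and coagulation genes (9, median 0.33). The same held for 9 of 19 endothelial activation genes (9 adjusted over the list alone, median 0.35) and 7 of 17 monocyte and macrophage markers (8, median 0.25). With an estimated correlation the adjusted p values of these 9 lists, in that order, were 0.00027, 0.0069, 0.0035, 0.023, 0.00015, 0.00015, 0.00015, 0.0018 and 0.00081. The calls on chemokines (adjusted p = 0.067 with an estimated correlation), cholesterol synthesis (0.064), oxidative phosphorylation (0.17), cell cycle (0.23), oligodendrocyte markers (0.23), T cell markers (0.32), cytokines (0.38), microglia markers (0.44) and immediate-early genes (0.72) were lost. Without the poorly correlated array of C57/B6 day 6 mouse 4, chosen after seeing the data, 623 interactions were positive and 525 negative, the reverse of the order with it. The count was 2423 without C57/B6 day 6 mouse 2, 696 without Balb/C uninfected mouse 3 and 669 without Balb/C day 6 mouse 2.

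**Figure D3:**
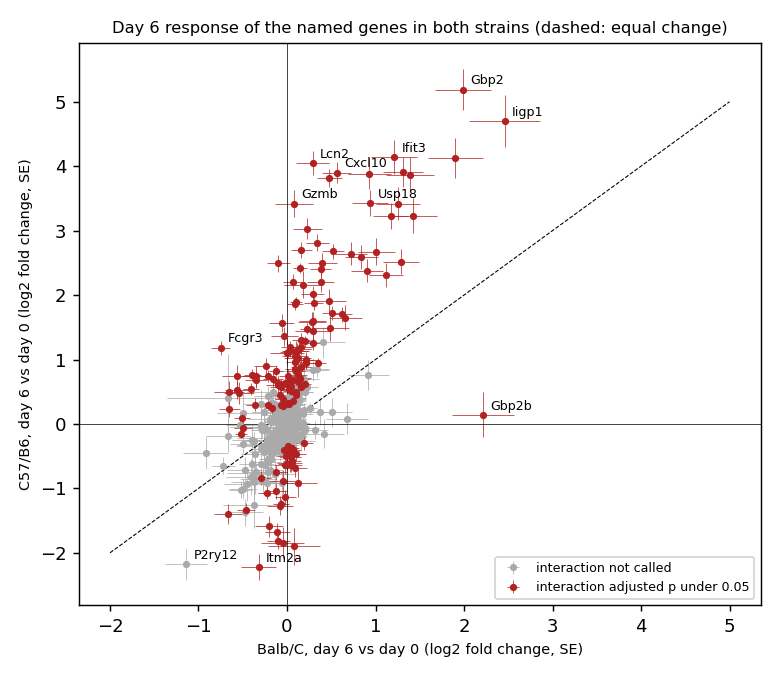
Each point is a named gene, with its day 6 log2 fold change in Balb/C mice on the x axis and in C57/B6 mice on the y axis, with SE bars (4 mice per group) and a dashed line of equal change. Red points had an interaction adjusted p under 0.05, such as Lcn2 with an interaction of 3.77.

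The same interaction was tested on the earlier days. On day 1 it passed for 13 genes, all of them positive, and 1109 had an unadjusted p under 0.05. The transcription factors Egr2 (log2 difference 2.03 ± 0.35, SE) and Nr4a1 (1.90 ± 0.39), both immediate-early genes, had the largest values, followed by the kinesin Kifc2 (1.12 ± 0.22). The log2 fold change of Egr2 was 0.89 in C57/B6 and -1.13 in Balb/C mice, that of Nr4a1 was 1.08 and -0.82, and that of Kifc2 1.06 and -0.06. The same 4 uninfected C57/B6 mice enter this interaction. The offset raised for them below may therefore contribute to these values, and this was not tested. Of the 19 immediate-early genes 2 passed (11 adjusted over the list alone, median 0.72), with a camera adjusted p of 5.3e-14 and an adjusted p of 0.18 with an estimated correlation. No gene passed in limma on day 3, where 422 had an unadjusted p under 0.05. The lists that passed camera were 7 on day 1 and 6 on day 3, and all of these calls were lost with an estimated correlation, with adjusted p values of at least 0.18 and 0.62. The day 1 count was 0 without any one of C57/B6 uninfected mouse 1 or 3, C57/B6 day 1 mouse 4 or Balb/C day 1 mouse 1 or 2, and 131 without C57/B6 uninfected mouse 2.

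The first days after infection were compared with day 0 in each strain. On day 1, 505 genes passed in C57/B6 mice (278 rose and 227 fell), and 36 of them by at least 1.5-fold. Arc (log2 fold change 1.49 ± 0.38, SE), Fos (1.30 ± 0.35) and Nr4a1 (1.08 ± 0.28), all induced by neuronal activity, had the highest values among called genes. Among genes whose infected and uninfected mice did not overlap, the largest rises were of Kifc2 (1.06 ± 0.15), the non-coding RNA Snhg11 (1.02 ± 0.21) and the nuclear envelope protein Syne1 (0.91 ± 0.09). The neurofilament genes Nefh (0.80 ± 0.12) and Nefm (0.63 ± 0.15) rose, and Folr1 (-0.65 ± 0.13), Pdlim2 (-0.54 ± 0.07), the cold-inducible gene Cirbp (-0.51) and Gpr37 (-0.47 ± 0.09) fell. Uninfected mice varied in Arc and Fos with an SD of 0.82 and 1 on the log2 scale, and those calls ended when single uninfected mice were left out. Of the 19 immediate-early genes 4 rose (7 adjusted over the list alone, median 0.32), of the 19 neuron markers 3 rose (4 and 1 fall adjusted over the list alone), of the 11 oligodendrocyte markers 3 fell (5 adjusted over the list alone), and of the 17 oxidative phosphorylation genes 1 fell (9 adjusted over the list alone). These 4 lists passed camera, with adjusted p values of 1.5e-06, 0.00034, 0.0048 and 7.7e-05, and all were lost with an estimated correlation (adjusted p = 0.77, 0.77, 0.77 and 0.82). Without uninfected mouse 2 the camera adjusted p for oligodendrocyte markers was 0.063.

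On day 3, 232 genes passed in C57/B6 mice (179 rose and 53 fell). Snhg11 (log2 fold change 1.06 ± 0.21, SE), Nefh (1.01 ± 0.12), Rock1 (1.01 ± 0.17), Syne1 (0.91 ± 0.09), Armcx4 (0.89 ± 0.14) and Nefm (0.78 ± 0.15) rose, and Cd53 (-0.58 ± 0.12), the glucocorticoid-induced Tsc22d3 (-0.50) and Fcrls (-0.45 ± 0.10) fell. Of the 19 neuron markers 2 rose (3 adjusted over the list alone, median 0.20) and of the 17 microglia markers 1 fell (6 adjusted over the list alone, median -0.25), with camera adjusted p values of 5.1e-05 and 8.5e-05, and adjusted p = 0.4 and 0.62 with an estimated correlation. Lists of oxidative phosphorylation, meningeal fibroblast and glucocorticoid-responsive genes also passed camera, and each call was lost with an estimated correlation (adjusted p = 1) and without uninfected mouse 4 (adjusted p = 0.11, 0.57 and 0.8). The calls on the first and second also ended without day 3 mouse 1 (0.065 and 0.065), that on the second without day 3 mouse 3 (0.23), and that on the last without day 3 mouse 1 (0.059), 2 (0.11) or 4 (0.11) and with the replicate block (0.08). Of the genes called, 181 were called on both day 1 and day 3 in the same direction, and 0 genes passed in limma between day 3 and day 1, where 237 had an unadjusted p under 0.05. Of the 181, 120 were also called between the uninfected mice of the strains, a comparison that uses the same uninfected C57/B6 mice, whereas 8 were called between the strains on day 1 and 9 on day 3. With the replicate number as a block the counts were 996 on day 1 and 479 on day 3, and leaving out 1 mouse gave 180 to 986 and 107 to 549 genes.

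In Balb/C mice 2 genes fell on day 1, Fcgr3 (log2 fold change -0.65 ± 0.11, SE, adjusted p = 0.02) and Tyrobp (-0.55 ± 0.10, adjusted p = 0.029), a signalling adaptor of myeloid cells, and 391 genes had an unadjusted p under 0.05. The count was 0 with the second array of each mouse alone and without any one of Balb/C uninfected mouse 1, 3 or 4 or day 1 mouse 1 or 3, 1 without day 1 mouse 2, and 36 with array weights. Of the 17 microglia markers Tyrobp fell (10 adjusted over the list alone, median -0.30) and all 17 had negative values, with a camera adjusted p of 1.4e-27, and 0.00042 with an estimated correlation. Of the 10 lists that passed camera this was the 1 that passed with an estimated correlation, and the next, circadian clock genes, had an adjusted p of 0.16. No gene passed in limma on day 3, where 447 had an unadjusted p under 0.05. The 19 immediate-early genes had no call over all genes and 8 falls adjusted over the list alone on day 3 (median -0.36), with a camera adjusted p of 1.2e-16 and an adjusted p of 0.16 with an estimated correlation.

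What set the strains apart before infection was also compared. Between uninfected mice 1110 genes passed, 569 of them higher in C57/B6 and 541 higher in Balb/C mice, and 23 and 19 by at least 2-fold. Rpgrip1 was higher in C57/B6 mice by a log2 difference of 4.63 ± 0.17 (SE, n = 4), with 9.52 ± 0.21 (SD) against 4.89 ± 0.07. Pttg1 (2.85 ± 0.13), Arl2bp (2.44 ± 0.10), Stk25 (2.28 ± 0.10) and Pdxdc1 (2.21 ± 0.11) were also higher, although another probe set of Pdxdc1 differed in the opposite direction. Cap1 (-3.57 ± 0.13), Gnb1 (-3.46 ± 0.18), Kcnj9 (-2.57 ± 0.13), Tmem87a (-2.35 ± 0.10) and Pisd-ps3 (-2.14 ± 0.11) were lower in C57/B6 mice. A probe set that spans a sequence difference between strains can give such a value without a difference in RNA. For the 25 genes that differed by at least 2-fold and have other probe sets, 19 of 42 other probe sets (45.2%) were called in the same direction, against 70 of 94 (74.5%) for genes changed by at least 2-fold on day 6 in C57/B6 mice. By gene, 16 of 25 had at least 1 other probe set called in the same direction, against 48 of 57. Among immune genes, Il33 (1.46 ± 0.22), Fcrls (1.41 ± 0.10), C1qb (1.14 ± 0.17) and B2m (0.76 ± 0.19) were higher and Serpina3n (-1.08 ± 0.10) was lower in C57/B6 mice. The neurofilament genes Nefh (-0.98 ± 0.12) and Nefm (-0.63) were lower. Both rose in C57/B6 mice on days 1 and 3. The mean of the neuron markers in C57/B6 mice was 9.53 uninfected, 9.74 on day 1 and 9.76 on day 3, beside 9.78 in uninfected Balb/C mice. Fewer genes passed between the strains on day 1 (533) and day 3 (480). The offset of the uninfected C57/B6 mice raised below may therefore enter these differences. Microglia markers as a list were higher (5 of 17, camera adjusted p = 0.0038) and neuron markers lower (3 of 19, adjusted p = 0.0038), and both calls were lost with an estimated correlation (adjusted p = 0.98).

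The strain labels were checked with H2-Ea, an MHC class II gene whose expression is removed by a deletion in C57BL/6 mice. The probe set used for this gene gave 6.81 ± 0.16 (SD, n = 4) in C57/B6 and 7.02 ± 0.09 in Balb/C uninfected mice, and no difference was called. Another of its 3 probe sets was lower in C57/B6 mice on day 0 (4.24 ± 0.08 against 4.87 ± 0.19), with differences of -0.63, -0.53, -0.50 and -0.61 on days 0, 1, 3 and 6 (adjusted p over all probe sets 0.0018, 0.014, 0.026 and 0.0014). The third was not called on day 0 (3.95 against 3.98).

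The strains were compared in the same way after infection. On day 1, 533 genes passed (297 higher in C57/B6 mice), and 8 of 17 microglia markers were higher (11 adjusted over the list alone, median 0.39), with a camera adjusted p of 0.012 with an estimated correlation. Immediate-early genes were higher for 8 of 19 (10 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.44). On day 3, 480 genes passed (277 higher), and endothelial cell markers passed camera (adjusted p = 0.0027), a call lost with an estimated correlation (adjusted p = 0.42). On day 6, 2164 genes passed, 924 of them higher and 1240 lower in C57/B6 mice. By at least 1.5-fold 297 were higher and 171 lower, and by at least 2-fold 126 and 35. On this day 17 lists passed camera, 9 of them with an estimated correlation. Lcn2 (log2 difference 3.84 ± 0.19, SE), Gzmb (3.34 ± 0.21), Cxcl10 (3.34 ± 0.16), Cxcl9 (1.64) and Icam1 (1.25) were higher and Alas2 (-1 ± 0.21) was lower in C57/B6 mice. Without the poorly correlated array of day 6 mouse 4, chosen after seeing the data, 1077 genes were higher and 981 lower. Without C57/B6 day 6 mouse 2 the count was 3311.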

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

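The tests of an offset of the uninfected C57/B6 mice, of the poorly correlated array, of a loss of hybridisation, of other probe sets taken by gene and of day 6 against days 1 and 3 were chosen only after the results were seen. The other tests were chosen before.

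A difference between the strains, tested by the interaction, drew attention to 13 genes on day 1 and 1050 on day 6, and to 7 lists on day 1 and 6 lists on day 3. With an estimated correlation 0 of the 7 and 0 of the 6 passed, and 9 of the 18 lists that passed on day 6. On day 6 the median interaction of the lists that passed camera was 1.5 for type I interferon-stimulated genes, 1.24 for interferon-gamma-induced genes, 1.10 for glucocorticoid-responsive genes and 1.08 for MHC class I genes. It was 0.57 for reactive astrocyte genes, 0.35 for endothelial activation, 0.34 for MHC class II genes, 0.33 for complement and coagulation and 0.26 for chemokines. It was 0.25 for monocyte and for microglia markers, 0.24 for immediate-early genes, 0.18 for T cell markers, 0.17 for cell cycle genes and 0.09 for cytokines. It was -0.17 for oligodendrocyte markers, -0.21 for oxidative phosphorylation and -0.42 for cholesterol synthesis. The calls on immediate-early genes, microglia markers and cytokines were each lost when 1 mouse was left out. For microglia markers the adjusted p was 0.3 without C57/B6 day 6 mouse 2 and 0.053 without C57/B6 uninfected mouse 4, and for cytokines it was 0.12 without C57/B6 day 6 mouse 4. For immediate-early genes 8 mice each ended the call. They were C57/B6 uninfected mice 1 (0.16), 2 (0.15) and 3 (0.05), C57/B6 day 6 mice 1 (0.094) and 2 (0.053), Balb/C uninfected mouse 4 (0.19) and Balb/C day 6 mice 1 (0.2) and 2 (0.058).

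The genes drawn out by the day 6 interaction were, with positive values, Lcn2 (3.77), Gbp6 (3.35), Gzmb (3.34), Cxcl10 (3.33), Gbp2 (3.20), Oasl2 (2.95), Ifit3 (2.92), Ctla2a (2.80), Irgm1 (2.60) and Cdkn1a (2.59). With negative values they were Gbp2b (-2.07), Fabp7 (-1.97), Itm2a (-1.90), Ugt8a (-1.79), Serpinb1a (-1.71), Slco1c1 (-1.57), Trim59 (-1.39), Nectin3 (-1.18), Gpr37 (-1.18) and Aspa (-1.11).

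A mouse far from the other 3 of its group was found in 21 of 408 groups of values, where chance alone would give about 1 in 20, or 20.4. In uninfected C57/B6 mice, mouse 2 was low in erythroid markers (5.57), heme and iron genes (7.05) and Cxcl9 (5.48), and mouse 4 was high in glucocorticoid-responsive (7.97) and hypoxia-inducible genes (8.46). On day 1 C57/B6 mouse 2 was low in olfactory bulb markers (6.41) and Tnf (6.06), and mouse 4 was low in cerebellum markers (8.30). On day 3 C57/B6 mouse 2 was high in unfolded protein response genes (8.52) and mouse 4 in heme and iron genes (7.07). On day 6 C57/B6 mouse 2 was low in cerebellum (7.50) and olfactory bulb markers (6.39) and high in Cxcl10 (8.99), mouse 3 was high in circadian genes (7.82) and mouse 4 in pericyte markers (6.68). In Balb/C mice, uninfected mouse 1 was high in oxidative phosphorylation genes (11.66), day 1 mouse 2 in interferon-gamma-induced genes (6.06) and day 1 mouse 3 in Hmox1 (5.67). Balb/C day 3 mouse 2 was high in olfactory bulb markers (6.93), day 3 mouse 4 in cerebellum markers (9.28) and day 6 mouse 3 in cytokines (5.24).

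A signal was also present in data that the comparisons did not use. Of 2246 probe sets with no gene or several genes, 484 were called in C57/B6 mice on day 6 (196 higher and 288 lower) and 6 in Balb/C mice. Of the 691 with several genes 220 were called in C57/B6 mice.

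The early changes in C57/B6 mice have an open technical explanation. Both days are compared with the same 4 uninfected mice, and 120 of the 181 genes called on both days also differed between the uninfected strains, against 8 on day 1 and 9 on day 3, a contrast that reuses the mice the genes were chosen with. When the genes (17 to 259) were chosen with 2 of the uninfected C57/B6 mice and the strains compared with the other 2, the median strain difference on day 0 ran against the day 1 change in all 6 splits, from -0.56 to -0.15, beside 0.07 to 0.09 on day 1 and -0.09 to -0.02 on day 3. These values are consistent with an offset of the uninfected C57/B6 mice, while a response of C57/B6 mice toward the Balb/C level on both days stays open as an untested biological explanation. Over genes the day 1 and day 3 changes correlated at 0.83, against 0.5 in unchanged groups simulated with shared uninfected mice, and 0 genes were called by limma between the days (237 at an unadjusted p under 0.05). With different uninfected mice for each day the correlation was 0.5 (mean of 6 splits), and the covariance 0.0109 against 0.0151 with the same mice. Sharing the same individual mice thus does not account for all of the agreement, which an offset common to them could also give. Leaving out the day 1 array with a high 3′ to 5′ ratio (0.55 against at most 0.14) gave 422 genes on day 1, so its part in the day 1 calls cannot be told apart from a change on that day, since fewer calls also follow from fewer arrays.

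The excess of falls over rises in C57/B6 mice on day 6 was set against 1 array. The second array of day 6 mouse 4 had a compressed range, with a median log2 difference from its duplicate of 0.45 in genes of low and -0.58 in genes of high intensity. Without it 1730 genes still fell and 1449 rose, against 2155 and 1393 with it. Of the 1730, 1614 had been called lower with it, so that array alone is argued against as the source of these falls. The excess of falls over rises shrank, however. With the first array of each mouse alone, which also leaves out that array, 1136 fell and 1047 rose. How much of the excess came from that array therefore stays open. When day 6 was compared with the mean of days 1 and 3 in place of day 0, 2754 genes were called (1189 higher and 1565 lower). Of these, 834 of the higher and 1194 of the lower had the same call against day 0 and 3 genes had the opposite call. Both comparisons use the same day 6 mice, with that array included. The shared calls are therefore in part built in, and they do not bear on the array. Of the 181 early genes, 151 were called in the same direction on day 6 against day 0, so that the offset discussed for the early days may enter day 6 for these too.

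The strain differences on day 0 were weighed against probe sequence. Among genes that differed by at least 2-fold, 45.2% of other probe sets of the same genes (19 of 42, 95% confidence interval 29.8 to 61.3) were called in the same direction, below the 74.5% for genes changed by at least 2-fold on day 6 in C57/B6 mice (Fisher's exact test, two-sided, p = 0.0016), where the interval and p take probe sets of 1 gene as independent. With whole genes permuted the gap in that share had p = 0.0052 (permutation test), but at least 1 other probe set was called in the same direction for 16 of 25 genes against 48 of 57 (p = 0.079, Fisher's exact test). Since these tests differ, probe sequences that differ between the strains cannot be told apart from differences in RNA as a source. A loss of hybridisation in Balb/C mice alone is argued against as the whole source, because the share of the 42 genes with higher values in C57/B6 mice was 0.548.

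For the counts of genes, other groupings of the same mice were tried. In each of these comparisons 1 of the 35 splits, the real one, gave as many calls. That is the smallest share that 35 splits allow, and the mice were not fully exchangeable, so it does not by itself exclude chance. The real counts and the highest of the other splits were 505 and 84 for C57/B6 day 1, 232 and 204 for day 3, and 3548 and 3395 for day 6. They were 30 and 19 for Balb/C day 6, 1110 and 49 between the strains on day 0, 533 and 1 on day 1, 480 and 0 on day 3 and 2164 and 2144 on day 6. For Balb/C day 1 the real split gave 2 and the highest other 0, which is 1 of 35 as well, but the count of 2 was 0 without any one of Balb/C uninfected mouse 1, 3 or 4 or day 1 mouse 1 or 3, so no weight is put on that share. For C57/B6 day 6 and the strains on day 6, the highest other split exchanged C57/B6 day 6 mouse 2 with a mouse of the other group. For Balb/C on day 3, 0 genes were called, so that all 35 splits give at least as many (highest other 0) and the splits say nothing about chance. Where the numbers pair the mice, the highest count among the other splits that part all 4 pairs was 0 for C57/B6 day 1 and day 3 and 13 for Balb/C day 6. Each has 8 such splits, the real one included, so 1 in 8 is the smallest possible share and cannot exclude chance. For the interactions 100 splits were drawn. On day 1 the real split gave 13 and the highest other 0, but the count was 0 without any one of C57/B6 uninfected mouse 1 or 3, C57/B6 day 1 mouse 4 or Balb/C day 1 mouse 1 or 2, so no weight is put on that share. On day 3 the real split gave 0 and the highest other 2, and since all 100 give at least 0 the splits say nothing about chance. On day 6, 2 of the 100, the real one included, gave as many as the real 1050. Such a share can exclude a random grouping of exchangeable mice, but the mice were not exchangeable, since the highest other gave 2200. That split exchanged C57/B6 day 6 mouse 2 with Balb/C day 6 mouse 3 and C57/B6 uninfected mouse 1 with a Balb/C uninfected mouse, which points to a structure among the samples beside strain and day.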

How the results depend on the processing

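The settings that leave out 1 or 2 arrays, alone or with the replicate block, were chosen after seeing the data, and the other settings before. Every count of genes moved by more than 1.5 times under at least 1 setting, and the cause was not tested unless the setting itself lowers it by construction (fewer arrays, a stricter threshold). Values below are given for C57/B6 mice, then Balb/C mice, then between the strains, then the interaction.

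With the first technical array of each mouse alone, 193, 135 and 2183 genes passed in C57/B6 mice on days 1, 3 and 6, 725 between the strains on day 0, and 3 and 595 for the interaction on days 1 and 6. With the second array alone these were 69, 52 and 2263 in C57/B6 mice, 0 and 11 in Balb/C mice on days 1 and 6, 425, 225, 193 and 1185 between the strains on days 0, 1, 3 and 6, and 1 and 336 for the interaction on days 1 and 6. At an adjusted p under 0.01 they were 137, 98 and 2101 in C57/B6 mice, 0 and 15 in Balb/C mice on days 1 and 6, 586, 320, 313 and 1284 between the strains, and 0 and 443 for the interaction on days 1 and 6. With a change of at least 1.5-fold required as well, they were 36, 32 and 509 in C57/B6 mice, 1 in Balb/C mice on day 1, 163, 163, 132 and 468 between the strains, and 7 and 364 for the interaction on days 1 and 6.

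With array weights 1726 and 1161 genes passed in C57/B6 mice on days 1 and 3, 36, 41 and 66 in Balb/C mice on days 1, 3 and 6, 2009, 1236 and 1044 between the strains on days 0, 1 and 3, and 652, 35 and 1905 for the interaction. With the groups of a contrast alone in the model 43, 73 and 821 passed in C57/B6 mice, 22, 11 and 4 in Balb/C mice, 759 between the strains on day 6, and 0 and 381 for the interaction on days 1 and 6. With all arrays and the mouse as a random block 354 passed in C57/B6 mice on day 3, 14, 22 and 55 in Balb/C mice, and 99 and 2 for the interaction on days 1 and 3. Quantile normalization applied again gave 4 in Balb/C mice on day 1 and 54 for the day 1 interaction (42 positive and 12 negative). The low-value filter gave 5 and 20 for the same comparisons. The mean of all probe sets gave 5 and 1 in Balb/C mice on days 1 and 3, and leaving out the suffixes s, x and a gave 6 and 2.

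With the replicate block 996 and 479 genes passed in C57/B6 mice on days 1 and 3, 13 and 7 in Balb/C mice on days 1 and 3, 1781 between the strains on day 0, and 113 and 1842 for the interaction on days 1 and 6. Other counts stayed within 1.5 times. Of the lists in the contrasts where the numbers pair the mice, the block ended the calls on glucocorticoid-responsive genes in C57/B6 mice on day 3 (adjusted p = 0.08) and in Balb/C mice on day 6 (0.074) and on olfactory bulb markers in Balb/C mice on day 6 (0.064). It added heat shock proteins in C57/B6 mice on day 1 (0.041). Elsewhere the mice share a number, and 22 of the 32 mice deviated on average most like the mice of their own number. The mean correlation was 0.05, 0.48, 0.15 and 0.24 for numbers 1 to 4.

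Without the second array of C57/B6 day 6 mouse 4, 861 and 479 genes passed in C57/B6 mice on days 1 and 3, 5 and 13 in Balb/C mice on days 1 and 3, and 64 for the day 1 interaction. Without that array and the second array of C57/B6 day 1 mouse 3 these were 800 and 487, 6 and 3, and 31. With the replicate block and without the first of these arrays they were 1611 and 952 in C57/B6 mice, 27, 18 and 53 in Balb/C mice, 2456, 1122 and 892 between the strains on days 0, 1 and 3, and 345, 2 and 1931 for the interaction. These contrasts share 1 estimate of spread, into which that array enters.

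The side with more calls on day 6 depended on the setting. Fewer rises than falls in C57/B6 mice became more rises with the groups of the contrast alone (429 and 392). Between the strains more genes were higher than lower with the first array alone (810 and 700), with the groups of the contrast alone (455 and 304), without the first doubted array (1077 and 981), without both (1072 and 991), with at least 1.5-fold required (297 and 171), at an adjusted p under 0.01 (650 and 634) and without C57/B6 day 6 mouse 4 (963 and 817). For the interaction more were positive with quantile normalization again (594 and 528), without suffixes s, x and a (395 and 394), with the first (383 and 212) or second array alone (223 and 113), with the groups alone (271 and 110), without the first doubted array (623 and 525), without both (626 and 525), with at least 1.5-fold required (226 and 138) and at an adjusted p under 0.01 (304 and 139). The same held without C57/B6 uninfected mouse 2 (489 and 441), 3 (425 and 402) or 4 (448 and 362), C57/B6 day 6 mouse 1 (428 and 396) or 4 (549 and 334), Balb/C uninfected mouse 2 (443 and 427), 3 (405 and 291) or 4 (441 and 427), and Balb/C day 6 mouse 1 (407 and 333), 2 (395 and 274) or 4 (436 and 415).

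Leaving out 1 mouse at a time gave 180 to 986, 107 to 549 and 2646 to 5244 genes in C57/B6 mice on days 1, 3 and 6, and 0 to 8, 0 to 11 and 15 to 46 in Balb/C mice. Between the strains it gave 811 to 1648, 399 to 794, 359 to 638 and 1650 to 3311, and for the interaction 0 to 131, 0 to 21 and 669 to 2423. In C57/B6 mice the day 1 count was 180, 280 and 192 without uninfected mouse 1, 3 or 4, 283, 193 and 251 without day 1 mouse 1, 3 or 4, and 986 without day 6 mouse 4. The day 3 count was 107, 510, 119 and 130 without uninfected mouse 1, 2, 3 or 4, 135 without day 3 mouse 3 and 549 without day 6 mouse 4. In Balb/C mice the day 1 count was 0 without Balb/C uninfected mouse 1, 3 or 4 or day 1 mouse 1 or 3, 1 without day 1 mouse 2, 4 without day 6 mouse 3 or C57/B6 uninfected mouse 1, 7 without C57/B6 uninfected mouse 4, and 5 and 8 without C57/B6 day 6 mouse 2 or 4. The day 3 count was 1 without C57/B6 uninfected mouse 2 or 4 and 11 without C57/B6 day 6 mouse 4. The day 6 count was 15, 16 and 46 without Balb/C day 6 mouse 1, 2 or 4. Between the strains on day 6 it was 3311 without C57/B6 day 6 mouse 2. The day 1 interaction was 0, 131, 0 and 35 without C57/B6 uninfected mouse 1, 2, 3 or 4, and 7, 45, 3 and 0 without C57/B6 day 1 mouse 1, 2, 3 or 4. It was 89 without C57/B6 day 6 mouse 4, 8, 3 and 4 without Balb/C uninfected mouse 2, 3 or 4, and 0 without Balb/C day 1 mouse 1 or 2. The day 3 interaction was 21 and 1 without C57/B6 uninfected mouse 2 or 4. The day 6 interaction was 2423 without C57/B6 day 6 mouse 2, 696 without Balb/C uninfected mouse 3 and 669 without Balb/C day 6 mouse 2.

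With the directional fry test 0 of 4, 0 of 5 and 19 of 19 lists kept their camera call in C57/B6 mice on days 1, 3 and 6, and 1 of 10, 0 of 1 and 4 of 17 in Balb/C mice. For the interaction it was 0 of 7, 0 of 6 and 15 of 18. The mean of all probe sets lost 3 of 5 lists in C57/B6 mice on day 3 and 6 of 17 in Balb/C mice on day 6. For lists, too, only mice of the groups compared were left out in turn. A camera call was lost without at least 1 of them for 1 of 4 lists in C57/B6 mice on day 1, 3 of 5 on day 3 and 1 of 19 on day 6. The same held for 7 of 10 in Balb/C mice on day 1 and 10 of 17 on day 6, and for 3 of 18 in the day 6 interaction. For named genes only mice of the groups compared were left out in turn. Of those called in C57/B6 mice on day 6, 103 of 125 were called without any 1 of these mice and in each setting run for single genes. On day 1 this held for 5 of 23 and on day 3 for 4 of 12. The same held for 9 of 25 in Balb/C mice on day 6, 23 of 54 between uninfected strains and 57 of 88 for the day 6 interaction. Those settings do not include array weights, the groups of a contrast alone, stricter thresholds or a changed variance model. With the groups alone 0 genes rose and 4 fell in Balb/C mice on day 6, and 1 of the 30 calls was made again. Leaving out suffixes s, x and a turned the sign for Acta2 in C57/B6 mice on day 6 (0.12), between the strains on day 0 (-0.08) and for the day 6 interaction (0.04), and for Aldh1l1 in the day 6 interaction (-0.11), since it puts another probe set in their place. Pitx1 in C57/B6 mice on day 6 was 0 with the first array alone. Genes near the lowest intensities, such as Ifng, carry little signal over background, which limits the size of a change that can be seen.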

Other observations

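The interferon response of Balb/C mice on day 6 differed in size between mice. The mean of the 27 type I interferon-stimulated genes was 6.54, 6.18, 5.93 and 5.59 in the 4 mice, against 5.55 to 5.66 in uninfected Balb/C mice. In C57/B6 mice the same mean was 7.57 to 7.73 on day 6 and 5.68 to 5.73 without infection, so that the highest Balb/C mouse lay below the lowest C57/B6 mouse.

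Microglia markers in Balb/C mice did not move in one direction over time. Their mean was 7.03 to 7.08 in uninfected mice, 6.58 to 6.75 on day 1, 6.96 to 7.01 on day 3 and 6.59 to 6.79 on day 6. In C57/B6 mice on day 6 members of the list went both ways, and fry's mixed test, which asks whether members change in either direction, gave an adjusted p of 2.4e-15. The same test gave 1.6e-13 for endothelial cell markers in C57/B6 mice on day 6. It does not compare a list with other genes, and 28.6% of all genes were called in that comparison. These values therefore do not set the microglia and endothelial lists apart from other genes. Neither list passed camera, which makes that comparison (adjusted p = 0.43 and 0.76).

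Gbp2b had values in C57/B6 mice near the lower end of the array on day 0 (4.14) and day 6 (4.28), and rose by 2.21 on the log2 scale in Balb/C mice. The array does not tell a gene that is not induced from one whose transcript the probes fail to bind in that strain, and this was not tested.

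No 2 arrays had identical values (0 pairs). The highest correlation between arrays of different mice was 0.9976 and that between the 2 arrays of a mouse 0.9979, and for 45 of the 64 arrays the most similar array came from another mouse.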
